A study of Mus musculus with 20 samples.

How the data were processed

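DNA methylation was measured by bisulfite sequencing of DNA from single mouse blastocysts, after the polyadenylated RNA of the same embryo had been taken off on beads. Per the labels, 10 embryos were controls (replicates 1 to 10) and 10 came from the Padi6-mutant group (replicates 11 to 20). Every embryo was treated as a separate replicate. The labels give neither the mother, the litter, the sex nor a sequencing batch of an embryo, so p-values measure the spread between these embryos, some of which can share a mother.

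Reads were trimmed with Trim Galore 0.4.4 and processed with Bismark 0.18.2 against mouse build GRCm39 (mm39), per the submitters' processing notes. The authors deposited a single table of methylation levels in percent, with a row per promoter window and a column per embryo, and with no value where an embryo gave none. How calls were combined within a window, whether a coverage minimum applied and how the windows were chosen are not given in the sources used here. The table has no read counts, so the depth behind each level is unknown and no binomial interval can be given. The number of windows with a value was used as the measure of coverage of an embryo. With few reads per window a level falls on coarse steps, and between 32.1% and 76.1% of the values of an embryo were exactly 0.

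The table held 54080 rows, of which 46 repeated another row in every column and were dropped, leaving 54034 windows of 3500 bp. Of the 492079 values, 1597 (0.325%) were whole numbers above 100, with 16 distinct values. No value in the table had exactly 3 decimals, whereas 5086 had 2 and 316 had 4, and 0 of the 1597 numbers exceeded 100 once divided by 1000. They were therefore read as percents that had lost their decimal point, and were divided by 1000. Leaving them out was tried as an alternative. No pair of embryos held copied values: the highest share of equal values between a pair, over windows where they were not both 0, was 4.48%.

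Windows are named by chromosome, start and end, with no gene name. The gene table at hand was on build GRCm38.p6, and the gene-proximal base of 239 windows (0.44%) met a gene end there, so coordinates could not be joined and windows are reported by position. The 19 gene lists fixed before the data were examined (imprinted, germline, lineage, housekeeping and others) were therefore not analysed here. The same holds for the spread of imprinted promoters and for their relation to the mean level across embryos.

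The main comparison used limma 3.58.1 in R 4.3.3 on the untransformed percent, with lmFit and eBayes at default settings, over windows with a value in at least 7 embryos of each group. Benjamini-Hochberg adjustment was applied over all tested windows and the threshold was an adjusted p under 0.05, with second counts that also required a difference of at least 10 or 20 percentage points. Tested on simulated data, in which the values of the 1620 windows were shuffled over embryos and chosen windows were raised in one group, the procedure recovered 47 of 100 windows raised by 20 points and 81 of 100 raised by 40 points, with 2 false calls, and made 0 calls when none was raised. Losses were not simulated. Windows of low level cannot fall by that much, so these rates do not give the recovery of losses. The rule for windows named in the text, fixed before the data were examined, takes the 8 largest decreases and the 8 largest increases past the threshold on autosomes; 3 windows met it. The other parts of the rule need gene names. Windows or regions named beyond these were chosen after their values were seen.

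The mean promoter methylation of an embryo was planned over windows with a value in all 20 embryos. There were 6 such windows, under the planned minimum, so the planned substitute was used: each value was taken as its deviation from the mean of its window over the embryos, the deviations were averaged over the 1620 windows, and the overall mean was added back. Values built from deviations in this way can fall slightly below 0 for small sets of windows. Group means were compared by two-sided permutation tests over embryos with 100000 resamples, or by exact permutation tests where a group held fewer than 10 embryos. Bootstrap intervals are at the 95% level. The same measure was used by bins of 10 percentage points of the mean level over all embryos and by chromosome, with Benjamini-Hochberg adjustment within each family. The mean over all embryos pools the values at hand, so it leans to the group with more of them; bins by the mean of the 2 group means were added as an alternative.

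Added after the data had been examined were the following. Windows were sorted into classes (under 5%, 5% to 20%, 20% to 50%, 50% or more) by their mean in 5 reference control embryos, with at least 3 of them giving a value. Levels were then read in the other 5 control embryos and in the mutant embryos, and the roles of the odd-numbered and even-numbered controls were swapped, so that no embryo was scored on windows it had helped to choose. A control embryo thus has its value from 1 reference set, and a mutant embryo the mean over both sets. The values of the groups are therefore not built alike, and each reference set was also used alone. Mean deviations per embryo over regions of 5 Mb, with at least 10 values per region and embryo, were compared with limma. Pearson correlations between embryos were taken across windows, over pairs with at least 500 shared windows. Embryos with more than 30000 windows with a value are called densely covered and the others sparsely covered. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps. Alternatives for the window filter, the scale, the normalization, the variance model, the test, the chromosomes and the embryos left out were also run.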

Results

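Promoter methylation was compared between single blastocysts from the maternal Padi6-mutant group and control blastocysts. PADI6 belongs to the peptidylarginine deiminase family and is an oocyte protein of the subcortical maternal complex, which the egg passes on to the embryo. The comparison asks whether promoter methylation at the blastocyst stage differs when the egg carried the mutation. Levels were deposited for 54034 promoter windows on build GRCm39 in 10 control and 10 mutant embryos. Read depth is unknown. Control embryos had a value in 4984 to 46950 windows (median 37253.5) and mutant embryos in 2875 to 43812 (median 12331.5). In the control group 6 embryos were densely covered (37049 to 46950 windows) and 4 sparsely covered (4984 to 17002). In the mutant group 3 were densely covered (38549 to 43812 windows) and 7 sparsely covered (2875 to 13847).

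Promoters that carry methylation in control blastocysts were less methylated in the mutant embryos. No such difference passed the test in the classes of promoters with little methylation. The classes were set by control levels alone, so any difference between the groups at single windows also widens this contrast. Over windows with a value in at least 3 embryos per group, placed by the mean of the 2 group means, no bin passed. There the mutant level was 78.5% of the control level under 10% and 98.9% at 50% to 60%. Over the 1620 windows placed that way, the 30% to 40% bin passed. Windows at 50% or more in the reference control embryos stood at 41.3% ± 6.58 (SD, n = 10) in the control embryos not used to choose them and at 24.3% ± 5.53 (SD, n = 10) in the mutant embryos. The difference was -17.0 percentage points (SE 2.72, bootstrap interval -22.2 to -12.0), which left the mutant embryos at 58.8% of the control level. All 10 mutant embryos lay below the control mean and 9 lay below the lowest control embryo. Windows at 20% to 50% in the reference controls stood at 26.6% ± 5.86 (SD, n = 10) in controls and 19.6% ± 4.25 (SD, n = 10) in mutants, a difference of -6.97 points (SE 2.29), with all 10 mutant embryos below the control mean. Windows at 5% to 20% differed by -0.55 points (13.1% ± 2.97 against 12.5% ± 2.96, SD, n = 10 each), and windows under 5% by 0.81 points (6.40% ± 1.40 against 7.21% ± 1.51, SD, n = 10 each).

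The 4 classes were compared by two-sided permutation tests with Benjamini-Hochberg adjustment. The adjusted p was 0.00012 for windows at 50% or more, 0.00492 at 20% to 50%, 0.691 at 5% to 20% and 0.304 under 5%. Within densely covered embryos alone the difference at 50% or more was -16.3 points (adjusted exact permutation p = 0.0476; the raw p of 0.0119 is the smallest that 6 against 3 embryos can give), and within sparsely covered embryos -21.4 points (adjusted exact permutation p = 0.0121). The 20% to 50% class lost its call among densely covered embryos (-7.34 points, adjusted exact permutation p = 0.119) and with odd-numbered reference controls alone (-4.20 points, adjusted exact permutation p = 0.132). In the comparisons by coverage the windows were still chosen by reference controls of both coverage classes. With 1 reference set at a time, both groups were read on the same windows. At 50% or more the difference was then -13.99 points with odd-numbered references (adjusted exact permutation p = 0.00266). With even-numbered references it was -20.02 points (adjusted exact permutation p = 0.00133).

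**Figure D1:**
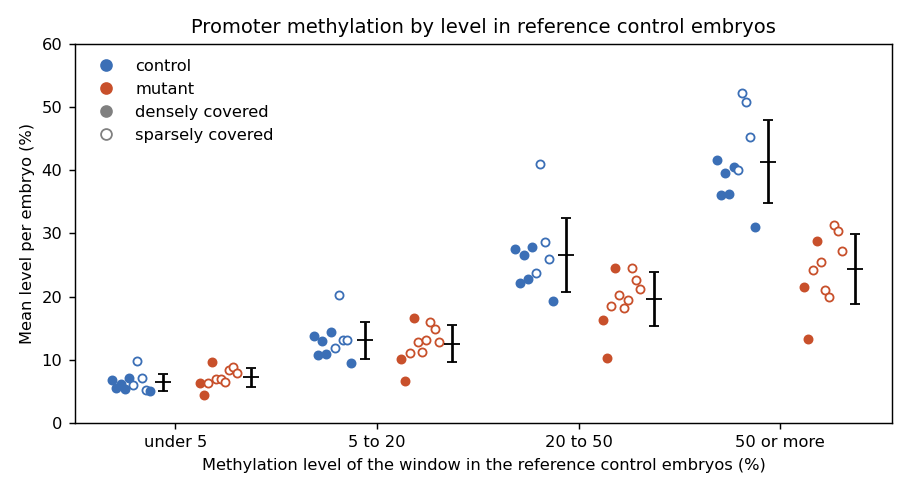
Mean methylation level per embryo in percent (vertical axis) in promoter windows sorted by their level in reference control embryos (horizontal axis, percent); blue points are control and red points mutant embryos, filled for densely and open for sparsely covered embryos, and black marks give the mean ± SD (n = 10 per group). At 50% or more the control embryos lie between 30.9% and 52.2% and the mutant embryos between 13.3% and 31.3%.

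The mean over all tested promoters did not separate the groups. Over the 1620 windows with a value in at least 7 embryos per group, it was 11.7% ± 2.35 (SD, n = 10) in control and 10.6% ± 2.14 (SD, n = 10) in mutant embryos. The difference of -1.09 points (SE 1.01, bootstrap interval -3.05 to 0.72) was smaller than the spread between embryos (permutation p = 0.305), and 7 of 10 mutant embryos lay below the control mean. Of these windows, 984 had a mean over all embryos under 10%, where both groups stood at 4.39%. Among sparsely covered embryos alone the difference was -3.11 points (exact permutation p = 0.0273), and among densely covered ones -1.74 points (exact permutation p = 0.381).

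Windows were also grouped by their mean over all values of the 20 embryos, a mean that leans to the control group where it has more values. The 83 windows at 30% to 40% stood at 40.2% ± 5.54 (SD, n = 10) in control and 30.2% ± 7.60 (SD, n = 10) in mutant embryos, a difference of -10.04 points (SE 2.97), and 9 of 10 mutant embryos lay below the control mean. This was the bin past the threshold among the 5 tested (adjusted permutation p = 0.0206). The 27 windows at 40% to 50% differed by -9.04 points and the 156 windows at 20% to 30% by -5.14 points, each with an adjusted permutation p of 0.187. The 367 windows at 10% to 20% differed by 0.46 points (adjusted permutation p = 0.994). Over the 37645 windows with a value in at least 3 embryos per group, the 40% to 50% bin passed as well (-12.4 points, adjusted permutation p = 0.0384), and a 50% to 60% bin of 214 windows stood at 66.4% ± 11.9 (SD, n = 10) in control and 50.9% ± 15.5 (SD, n = 10) in mutant embryos (-15.6 points, adjusted permutation p = 0.0398). With windows placed by the mean of the 2 group means, which weighs the groups equally, the 30% to 40% bin of the 1620 windows kept its call (-10.2 points, adjusted permutation p = 0.0199). Over the 37645 windows no bin passed with that placing: the difference was -1.07 points under 10% (4.99% against 3.92%, 9 of 10 mutant embryos below the control mean, unadjusted p 0.0278, adjusted permutation p = 0.0888), -8.38 points at 30% to 40% (adjusted permutation p = 0.0888), -7.03 points at 40% to 50% (0.364) and -0.68 points at 50% to 60% (0.918).

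Among single promoters, 3 windows of the 1620 tested passed the threshold in limma, and all 3 were lower in mutant embryos. The window on chromosome 4 from 154417584 to 154421083 stood at 39.1% ± 10.9 (SD, n = 7) in control and 4.96% ± 6.41 (SD, n = 7) in mutant embryos (-34.1 points, SE 4.70, limma adjusted p = 0.00845). Its control values ran from 25% to 50% and its mutant values from 0% to 13.9%. The window on chromosome 17 from 34255411 to 34258910 stood at 47.4% ± 10.1 (SD, n = 8) and 8.53% ± 17.3 (SD, n = 8), with a difference of -38.9 points (SE 6.83, limma adjusted p = 0.031). There 7 of 8 mutant embryos lay below the control mean, 5 of them at 0%, and the remaining one at 50%. The window on chromosome 11 from 63852052 to 63855551 stood at 58.3% ± 16.2 (SD, n = 8) and 15.0% ± 15.2 (SD, n = 7), with a difference of -43.3 points (SE 7.83, limma adjusted p = 0.0357) and 7 of 7 mutant embryos below the control mean.

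All 3 windows differed by more than 20 percentage points. At an unadjusted p under 0.05 there were 92 windows, of which 78 were lower and 14 higher in mutant embryos. This imbalance was not seen in densely covered embryos alone, where 1098 of 17634 windows had an unadjusted p under 0.05, 544 of them lower and 554 higher, and 2 passed the threshold, 1 lower and 1 higher. The window on chromosome 1 from 171554483 to 171557982, chosen after its values were seen, had 75.1% in control and 21.7% in mutant embryos and failed the correction (-53.4 points, SE 10.5, limma adjusted p = 0.0616). The count of 3 depends on the filter and on single embryos: with at least 3 embryos per group 14 windows passed, 11 lower and 3 higher, and 1 of the 3 windows was among them. An exact rank-sum test, limma with a variance trend and robust fitting, and quantile normalization each gave 0, and leaving out single embryos gave 0 to 5.

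**Figure D2:**
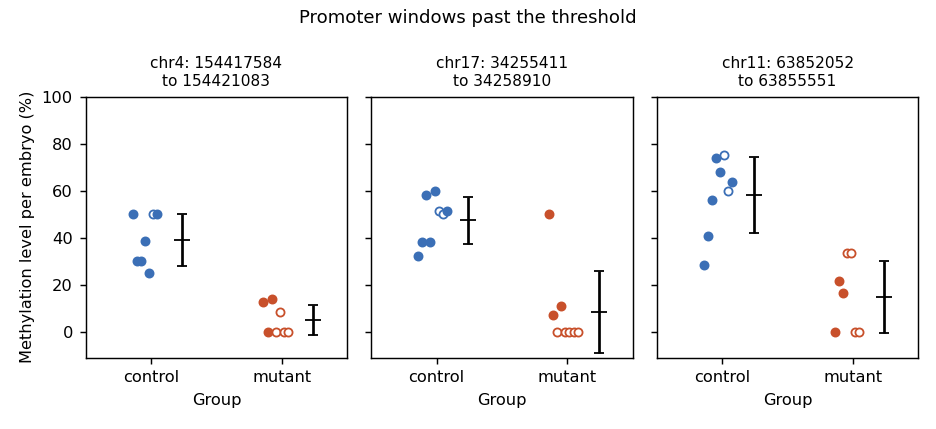
Methylation level in percent (vertical axis) of each embryo with a value in the 3 promoter windows past the threshold, for control (blue) and mutant (red) embryos; filled points are densely and open points sparsely covered embryos, and black marks give the mean ± SD. On chromosome 4 the control embryos start at 25% and the mutant embryos end at 13.9%, and on chromosome 17 one mutant embryo lies at 50%.

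Of 305 regions of 5 Mb tested, 2 passed the threshold and both were lower in mutant embryos. At an unadjusted p under 0.05 there were 39 regions, 39 lower and 0 higher, and 246 of the 305 (80.7%) had a lower mean. All regions share the same embryos, and 7 of 100 splits of the embryos, the real one included, gave as large a surplus of one direction among the regions with an unadjusted p under 0.05. The region on chromosome 12 from 105000001 to 110000000 had 171 windows and a difference of -17.8 points (SE 2.36, limma adjusted p = 1.92e-07), with 10 of 10 mutant embryos below the lowest control embryo. Over its non-overlapping windows the difference was smaller, at -10.35 points (limma adjusted p = 0.00349), with 7 of 10 mutant embryos below the lowest control embryo. The region passed with every single embryo left out. The region on chromosome 10 from 5000001 to 10000000 had 51 windows and a difference of -11.9 points (SE 2.72, limma adjusted p = 0.0105). This call was lost among densely covered embryos (-6.07 points, limma adjusted p = 0.353), and the region had too few values to be tested over non-overlapping windows or with any of 10 single embryos left out.

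Within the chromosome 12 region the difference was concentrated in 90 windows between 109503879 and 109993307, a stretch chosen after its values were seen, so its values are given without a test. Their plain mean per embryo was 49.2% ± 4.85 (SD, n = 10) in control and 14.5% ± 10.4 (SD, n = 10) in mutant embryos, a difference of -34.8 points. Control embryos ranged from 40.9% to 56.5% and mutant embryos from 0.0% to 27.6%. Of the 90 windows, 85 had a lower mean in mutant embryos, 74 of them by at least 10 points, and 5 a higher one. On the measure built from deviations, which was used for the region, the 90 windows differed by -32.05 points and the remaining 81 windows of the region by -4.73 points. Many of the windows overlap, and over 33 windows of the stretch that do not, the difference on that measure was -23.1 points; there the groups overlapped, with control embryos from 10.3% to 56.1%, mutant embryos from -6.65% to 28.9% and 3 of 10 mutant embryos below the lowest control embryo. The 2 mutant embryos at 0.0% had a value in 11 and 8 of the 90 windows.

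**Figure D3:**
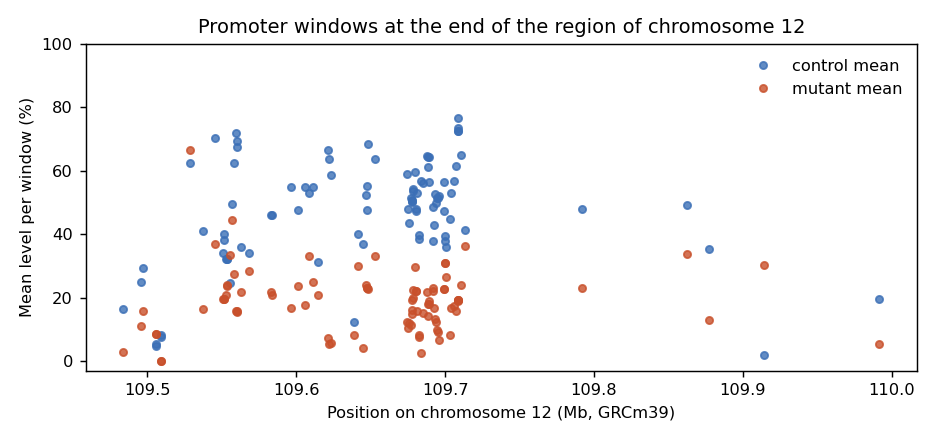
Mean methylation level in percent (vertical axis) of each promoter window with a value in at least 3 embryos per group, by position on chromosome 12 in Mb of build GRCm39 (horizontal axis), for control (blue) and mutant (red) embryos. In the 90 windows from 109503879 on, 85 mutant means lie below the control mean of the same window.

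Whole chromosomes gave no call. Of 20 chromosomes, 0 passed the permutation test after adjustment (smallest adjusted p 0.138), 3 had an unadjusted p under 0.05, and 16 had a lower mean in mutant embryos. Over windows with a value in at least 3 embryos per group, 0 passed, 4 had an unadjusted p under 0.05 and 19 were lower.

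Correlations across promoters were lower between mutant embryos than between control embryos. Whether this is separate from the lower levels at methylated windows, which narrow the range over which a correlation is taken, was not tested. The mean Pearson correlation across windows was 0.29 between control embryos (0.19 to 0.37, 45 pairs) and 0.10 between mutant embryos (0.02 to 0.18, 44 pairs), a difference of -0.19 (permutation p = 2e-05). Between control and mutant embryos it was 0.15 (0.05 to 0.23, 99 pairs). Windows are not independent replicates, so the test was made over embryos. Among densely covered embryos alone the means were 0.33 (15 pairs) and 0.12 (3 pairs), a difference of -0.20 with an exact permutation p of 0.0119, the smallest that 6 against 3 embryos can give.

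**Figure D4:**
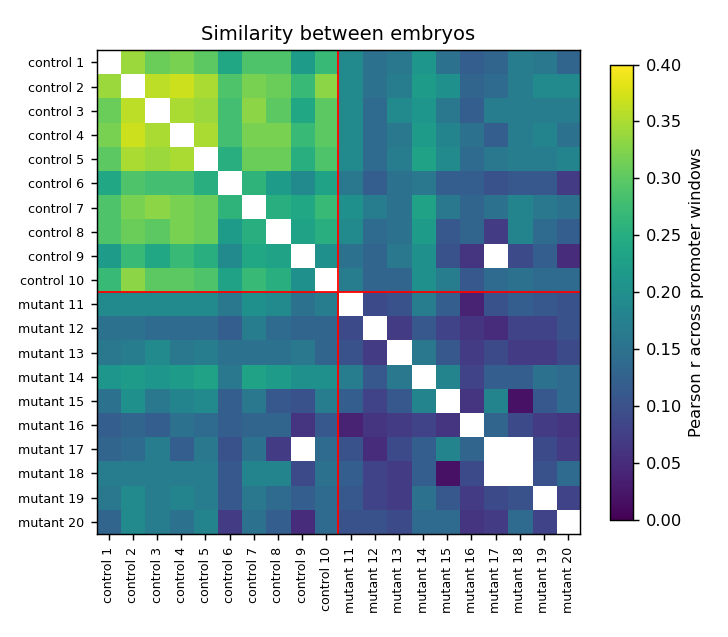
Pearson correlation (colour scale) across promoter windows for each pair of embryos, with control embryos 1 to 10 before mutant embryos 11 to 20 on both axes, red lines between the groups, and white cells on the diagonal and for pairs with fewer than 500 shared windows. Pairs of control embryos lie between 0.19 and 0.37 and pairs of mutant embryos between 0.02 and 0.18.

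The spread of mean promoter methylation between embryos was not distinguishable between the groups. The mean absolute deviation from the group median was 1.57 points in control and 1.54 points in mutant embryos (n = 10 each, permutation p = 0.968). This likeness may depend on control replicate 7, the highest control embryo, but the mean absolute deviation was not computed without it. With all embryos the SD of the mean level was 2.35 points in control and 2.14 points in mutant embryos. Without control replicate 7, over the 1422 windows left, it was 1.43 points in control (n = 9) and 2.27 points in mutant embryos (n = 10). That spread was not tested.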

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

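The test of exact 0% and 100% values below was written before its result was seen; the levels by reference class were added after the data were examined. Control replicate 7, a sparsely covered embryo, lay far above the other 9 control embryos in mean promoter methylation, at 17.1%. It also stood apart in windows under 5% in the reference controls (9.74%), at 5% to 20% (20.3%) and at 20% to 50% (41.0%). In each case its gap to the next control embryo exceeded 0.466 of the range of the group. Of 16 groups of values checked, 4 were past this limit, whereas chance gives about 1 in 20; the 4 come from the same embryo and are not independent. Without this embryo the difference in mean promoter methylation was -0.26 points (exact permutation p = 0.78).

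A technical candidate is coarse levels from few reads, since 8.92% of the values of this embryo were exactly 100. With values of exactly 0 and 100 left out, its gap fell to 0.24 of the range. This leaves the explanation open, because the other sparsely covered control embryos rose as well (23.2% to 24.8%, against 29.1% in replicate 7 and 11.3% to 18.6% in densely covered ones), which widened the range. The design gives no biological group within the controls, so no biological explanation was tested.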

How the results depend on the processing

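The comparisons by reference class, by 5 Mb region and by similarity, and the alternatives by coverage, by at least 5 or 6 embryos, by windows with at least 3 embryos for the mean, bins and chromosomes, by bins of the mean of the 2 group means, and by lost decimal points, were chosen after seeing the data; the others were fixed before the data were examined. No paired analysis was possible because control embryos carry the numbers 1 to 10 and mutant embryos 11 to 20, so no number is shared. The alternatives for gene lists were not run, since windows could not be tied to genes, and the alternative for the mean over at least 7 embryos per group became the main measure.

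The number of windows past the threshold, 3, was 0 of 6 with a value in all 10 embryos per group (1 at an unadjusted p under 0.05), 0 with at least 5 embryos (727 unadjusted), 0 after quantile normalization (99), 0 with trend and robust fitting (73) and 0 with the rank-sum test (122). It rose to 5 without windows under 5%, 6 with embryo quality weights, 8 with at least 6 embryos (7 lower, 1 higher, all 3 shared) and 14 with at least 3. It was 2 or 3 in the other 8, among them 1 lower and 1 higher in densely covered embryos. Leaving out single embryos gave 0 to 5: 0 without control 3, 4, 5, 7 or 10 or mutant 16, 19 or 20, 1 without mutant 11, 12, 14 or 15, and 5 without control 6 or mutant 18, with 381 to 1558 windows left to test. Counted per window and refit, the 3 windows had 82 estimates under alternatives, all 82 lower and 47 past the threshold. These are not independent checks, since the windows were picked for their difference on the same data. Some refits also left out an embryo with no value there. For the chromosome 4 window this held in all 6 refits with a single embryo left out, so its -34.1 points could not change. Without any embryo that had a value there, the window fell below 7 embryos in a group and was not tested.

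The mean level stayed lower and short of the threshold except in sparsely covered embryos (-3.11 points); leaving out single embryos gave -1.85 to -0.26. The 40% to 50% bin passed with at least 3 embryos per group (-12.4 points). With bins by the mean of the 2 group means and at least 3 embryos per group, the 30% to 40% bin no longer passed (-8.38 points). The class at 50% or more passed in all 26 alternatives (-21.4 to -14.0 points, and -18.2 to -15.8 with single embryos left out). In the alternatives by coverage and with single embryos left out, the classes were not chosen anew. An embryo was dropped from the comparison, but a dropped control still helped to choose the windows. The 20% to 50% class failed in densely covered embryos (-7.34) and with odd-numbered references (-4.20), and passed with every single embryo left out (-7.77 to -5.36). The number of 5 Mb regions, 2, was 1 with non-overlapping windows, 5 in densely covered embryos, and 1 to 3 with single embryos left out: 1 without control 3, 7 or 10 or mutant 11, 12, 13, 15, 16 or 19. The chromosome 10 region was not among those tested in these 9, nor without mutant 14, where another region made the count 2, nor with non-overlapping windows. Beyond fewer windows, embryos or regions to test, the cause of these changes was not tested. With no read counts, windows measured by few reads could not be set apart.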

Other observations

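The tests of sparse coverage and of proportional loss at windows methylated in controls were chosen only after the result was seen, as were the reliance on densely covered embryos and the test of like level over non-overlapping windows for chromosome 12 and the bins by the mean of the 2 group means; the other tests below were written before theirs. The splits of the embryos, the windows chosen by mutant embryos and the regions among densely covered embryos were not part of the planned comparisons.

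Windows chosen for a high level in some mutant embryos were more methylated in controls than in the other mutant embryos. In windows at 50% or more in 5 of the mutant embryos, taken in turn as reference (226 and 292 windows), the held-out mutant embryos stood at 20.6% ± 6.31 (SD, n = 10) and the control embryos at 30.6% ± 6.65 (SD, n = 10), a difference of -9.94 points (SE 2.90, permutation p = 0.00163), with all 10 mutant embryos below the control mean. Some windows were higher in mutant embryos. With a value in at least 6 embryos per group, 1 window of 8 past the threshold was higher, on chromosome 5 from 130412972 to 130416471 (9.21% ± 8.07 in control and 43.6% ± 8.51 in mutant embryos, SD, n = 6 each, limma adjusted p = 0.0317). The lower ones there included a window on chromosome 15 from 81558580 to 81562079, at 58.3% ± 19.5 in control and 2.86% ± 7.0 in mutant embryos (SD, n = 6 each, limma adjusted p = 0.0317). Among densely covered embryos 5 regions of 5 Mb passed, all lower, and the region on chromosome 12 was the only one of them to pass over all 20 embryos as well. The region from 55000001 on chromosome 7 had -14.2 points in densely covered embryos and -10.25 points over all embryos (limma adjusted p = 0.118), the one from 85000001 on chromosome 16 had -10.9 and -0.26 points (limma adjusted p = 0.985), and the one from 50000001 on chromosome 1 had -10.8 and -2.83 points (limma adjusted p = 0.693). The region from 100000001 on chromosome 6 had -11.9 points in densely covered embryos and was not among those tested over all embryos.

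The 3 windows past the threshold exceed what other splits of the 20 embryos gave: of 100 splits, 1, the real one, reached 3, and the highest other count was 2. For regions of 5 Mb 2 of 100 splits, the real one included, reached the real count of 2. Such a count was rare among the splits, but another split matched it, so the count alone does not exclude chance. Among the 9 densely covered embryos chance cannot be excluded, since 17 of 84 splits gave at least the 2 windows of the real split and the highest other gave 11. For the 5 regions among these embryos 2 of 84 splits gave as many, the real one included. The highest other gave 39 regions, with control 10 and mutants 11 and 12 on its smaller side, several times the real count and along a line that the groups do not follow. The surplus of lower over higher windows at an unadjusted p under 0.05 (64) was reached by 6 of 100 splits, with 74 as the highest other, so that surplus alone does not exclude chance. Nor does the surplus of lower regions at an unadjusted p under 0.05 (39), which 7 of 100 splits reached, with 129 as the highest other.

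The lower level at windows methylated in controls was weighed against 4 technical explanations. Sparse coverage of most mutant embryos does not account for it, because the smaller of the differences within densely and within sparsely covered embryos was still -16.3 points. A single proportional loss at every window, as over-conversion would give, could not be decided. The mutant to control ratio was higher by 53.8 percentage points (SE 6.7) in windows under 5% than in windows at 50% or more of the reference controls. It was read in embryos that had not chosen the windows. The windows were chosen by control levels alone, however, so any difference between the groups at single windows also widens this gap. Different windows covered in the groups are argued against by the mean of differences taken within each window (-13.2 points in the smaller of the reference sets). A pattern peculiar to each group without net loss was sought at windows at 50% or more in reference mutant embryos, where the difference was -9.94 points. Held-out mutant embryos stood at only 20.6% there. The choice thus largely failed to find windows methylated in them, and the test cannot decide. With bins by the mean of the 2 group means over at least 3 embryos per group no bin passed (-8.38 points at 30% to 40%). The mutant level was 78.5% of the control level under 10%, 97.0% at 10% to 20% and 89.1% at 20% to 30%. It was 80.0% at 30% to 40%, 86.6% at 40% to 50% and 98.9% at 50% to 60%. The size of the difference, and how it splits over levels, thus depend on how windows are chosen. Proportional loss, alone or combined with a higher background, and a pattern peculiar to each group stay open. So do litter, sex and handling, which the labels do not give. A loss of methylation tied to the maternal genotype may explain the pattern, as a hypothesis found on the same data.

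In the region of chromosome 12 from 105000001 to 110000000, reads counted in many overlapping windows do not account for all of the loss. Non-overlapping windows still differed by -10.4 points (SE 2.12). The difference over all windows was larger, at -17.8 points, so part of that size depends on the overlapping windows. That its windows are more methylated, and methylated windows lose more everywhere, does not account for the loss over all its windows, which beyond other windows of like level was -12.34 points (SE 2.63, limma adjusted p = 0.0195 over 305 regions; -14.2 points with levels by the mean of the 2 group means). Over non-overlapping windows this cannot be told apart: the -7.19 points there (SE 1.93, limma adjusted p = 0.213 over 270 regions) lie below the -2 points asked for beforehand by more than 2 SE, but that bound did not allow for the region having been picked as the most different one. To allow for it, each of 100 splits was searched for its own largest ratio of difference to SE. Over all windows the real split alone reached the 4.69 of this region (highest other 4.26). Such a ratio was thus rare among the splits, but 100 splits cannot show a share below 1 in 100, so chance is not excluded. Over non-overlapping windows 13 splits reached its 3.73 (highest other 4.96), so chance stays open there as well. Sparse coverage of most mutant embryos is argued against by the densely covered embryos, where the region differed by -16.9 points (SE 4.08); sparsely covered embryos on their own (-14.7 points, SE 5.92) did not meet the bound set beforehand, which had asked for both, although that coverage cannot act among densely covered embryos. Litter, sex and handling stay open here too. Distal mouse chromosome 12 carries the imprinted Dlk1-Dio3 domain, where the alleles of the parents differ in methylation. That these windows lie in it, and lost methylation of one parental allele, is a hypothesis that was not tested, as no annotation of build GRCm39 was used here.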
